A study of Mus musculus with 4 samples.

How the data were processed

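RNA immunoprecipitated with an anti-Cpeb4 antibody or control IgG from V-SVZ lysates of CD1 mice was measured in 4 libraries, 2 per antibody. Per the labels' protocols, the RNA was isolated with a MAGNA RIP kit, cDNA was made with the SMART-Seq v4 low input kit, which primes on poly(A) tails and does not mark strand, and libraries were prepared with Nextera XT. The submitters' processing notes name FastQC 0.11.5, Trim Galore 0.5.0, STAR 2.6.0c, HTSeq 0.6.1p2 and the genome build mm10, with no role or setting for any of them. In those notes the authors also name DESeq2 1.26.0. Low input amplification without molecular identifiers means that reads are not independent molecules.

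Per the file headers, the deposited table gives FPKM for each library and 53379 genes, and the authors' own comparison of Cpeb4 with IgG. The authors' mean level is a signal, the mean of reads divided by size factors, deposited for 30361 genes. Per the file headers, the deposited comparison also holds a log2 fold change with its standard error, a test score (the estimate divided by its standard error) and a p-value with its adjusted p-value. Per the labels, the samples are numbered by experiment, and the deposited table is named for a batch comparison. The deposited table held 0 columns of other samples. The FPKM of a gene falls in steps of 1 read, and joined to the authors' mean level these steps gave whole reads for 100% of values within 0.01 read. On simulated data with 30000 genes, 100% of reads were recovered. The deposited FPKM carry the size factors of the authors' mean level to within about 1% and not the read totals. The recovered reads gave depths of 22486721 to 35037171 reads per library and served for depth, for other scalings and for 1 alternative test. The planned edgeR and DESeq2 tests were not run, because the deposited unit was FPKM. The limma test used instead was written before the data were examined, for a table without counts from which whole reads cannot be recovered. Whole reads were recovered here, so the use of limma on FPKM as the main test departed from the plan.

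Genes with an FPKM of at least 1 in at least 2 libraries (15745 genes) were tested on log2(FPKM + 1) with limma 3.58.1 (R 4.3.3), with a trended prior, antibody as the effect and experiment as a block. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. A fold change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. The block left 1 residual degree of freedom per gene, and the prior taken from all genes added 14.6. The block was kept because the labels number the experiments across antibodies and the deposited table names a batch; the correlation of the deviations of same-numbered libraries from their group means, across genes, was 0.002, and 42 genes differed between experiments. Replicates were compared before averaging: the chi-square per degree of freedom was 23.0 for the Cpeb4 pair and 4.97 for the IgG pair, so neither pair was 1 library given 2 times. The Cpeb4 pair varied more, while the main test pooled the spread of both antibodies. On simulated data with 15745 genes, of which 200 were changed, in 5 tables, limma recovered 99.4% of genes changed by 1 and 100% of those changed by 2 on the log2 scale, and 6.38% of its calls were unchanged genes. The simulated noise was normal, took limma's own estimate of spread, was equal for both antibodies and held no experiment effect. Far fewer genes were changed than were called in the data, so these rates check the code and do not measure recovery in these libraries.

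Before the data were examined, 27 gene lists were fixed and tested with camera at a correlation of 0.01 between genes, with the correlation estimated per list and with fry as alternatives. The genes named were fixed by rule: Cpeb4, its paralogs and Eif4enif1, the 10 largest positive and 10 largest negative log2 fold changes among called genes with a mean log2(FPKM + 1) of at least 3 and the same sign in both experiments, without predicted gene symbols, the called members of each list with the smallest adjusted p, and the 5 genes with the smallest adjusted p, with ties taken by unadjusted p. The rule was written for log2 CPM and was applied to log2(FPKM + 1). Further list members that were lower, or that share reads with another gene, and the genes named among the other observations, were chosen after their values were seen. Some list members that the rule selects are not reported here. Scaling by read totals and by upper quartile, other filters, another pseudocount (0.1), limma-voom on the recovered reads, no block and leaving out each library were alternatives listed before the data were examined. Trimmed mean of M-values, centring on the median of tested genes, subtraction of the density on silent genes, and removal of a loess trend (span 0.5) on gene length and mean level were added after seeing the data. Gene length here is the length implied by the FPKM steps.

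Gene coordinates and biotypes came from a RefSeq gene table of GRCm38, the same assembly as mm10, matched by symbol for 14066 of 15745 tested genes. Cytoplasmic polyadenylation elements in 3′ untranslated regions, which needed a genome sequence, were not analysed here. Of the deposited symbols, 101 occur on more than 1 gene identifier, Dlx6os1 among them; both of its identifiers count as list members, and the one with the higher level is the one named. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.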

Results

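RNA bound to Cpeb4 was measured in the ventricular-subventricular zone (V-SVZ), the neurogenic tissue along the lateral ventricles, of wild-type CD1 mice at postnatal day 7 or 8. Cpeb4 is a cytoplasmic polyadenylation element-binding protein, a member of a family of RNA-binding proteins that act on 3′ untranslated regions to regulate poly(A) tail length and translation. Tissue lysates were immunoprecipitated with an antibody against Cpeb4 or with control IgG, and the recovered RNA was converted to cDNA and sequenced. The experiment was done 2 times, each with 1 Cpeb4 and 1 IgG library, which gave 2 libraries per antibody. The Cpeb4 libraries held 35037171 and 24483742 reads on genes and the IgG libraries 24094241 and 22486721, as recovered from the steps of the deposited FPKM (fragments per kilobase of gene, normalized for depth). The labels do not say that the experiments used separate animals, so p-values measure the spread between these samples, which may be technical. Across genes, log2(FPKM + 1) correlated at 0.987 between the Cpeb4 libraries, at 0.992 between the IgG libraries and at 0.923 to 0.946 between antibodies.

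The comparison of Cpeb4 with IgG immunoprecipitates asked which transcripts came down with Cpeb4 beyond the background recovered by IgG. Transcripts of the P-body helicase Ddx6, the CCR4-NOT deadenylase subunits Cnot7 and Cnot6l, the neuronal RNA-binding protein Elavl4, the neuroblast gene Dcx and Cpeb4 itself were higher in the Cpeb4 immunoprecipitates. Transcripts of the respiratory chain subunit Cox8a, the synaptic complexin Cplx2 and the noncoding RNA Gas5 were lower. Of 15745 genes tested with limma, 6106 were higher and 1822 lower in Cpeb4 immunoprecipitates at a Benjamini-Hochberg adjusted p under 0.05, and 7817 were not called. At least a 2-fold change accompanied 1704 of the higher and 279 of the lower calls, and at least a 4-fold change 40 and 19. Of 7928 called genes, 7916 had the same sign in both experiments. The calls rest on the mean of these same differences, so this agreement was nearly fixed by the selection. Over all tested genes, the fold changes of the 2 experiments had a Pearson correlation of 0.86.

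The split between higher and lower calls depended on how the libraries were scaled. With the authors' scaling, 77% of calls were higher and the median log2 fold change of tested genes was 0.19. With libraries scaled to their read totals, 2759 genes were higher and 6670 lower, so that 29.3% of calls were higher, and the median was -0.24. The upper quartile gave 3101 higher and 5841 lower (34.7% higher, median -0.18), trimmed mean of M-values 4089 and 3900 (51.2%, median -0.04) and centring on the median of tested genes 3718 and 4715 (44.1%, median -0.09). Each of the other 4 scalings moved the Cpeb4 libraries down and the IgG libraries up, so they could end calls of higher genes but not of lower ones. Of the 6106 genes called higher, 2748 were higher under all 5 scalings. The median log2 fold change was 0.19 without IgG replicate 1 and 0.18 without IgG replicate 2. It was 0.18 without Cpeb4 replicate 1 and 0.21 without Cpeb4 replicate 2. In these fits the spread came from the complete pair alone. The Cpeb4 pair varied more than the IgG pair (chi-square per degree of freedom 23.0 against 4.97), so their counts of calls do not show which libraries drive the calls.

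**Figure D1:**
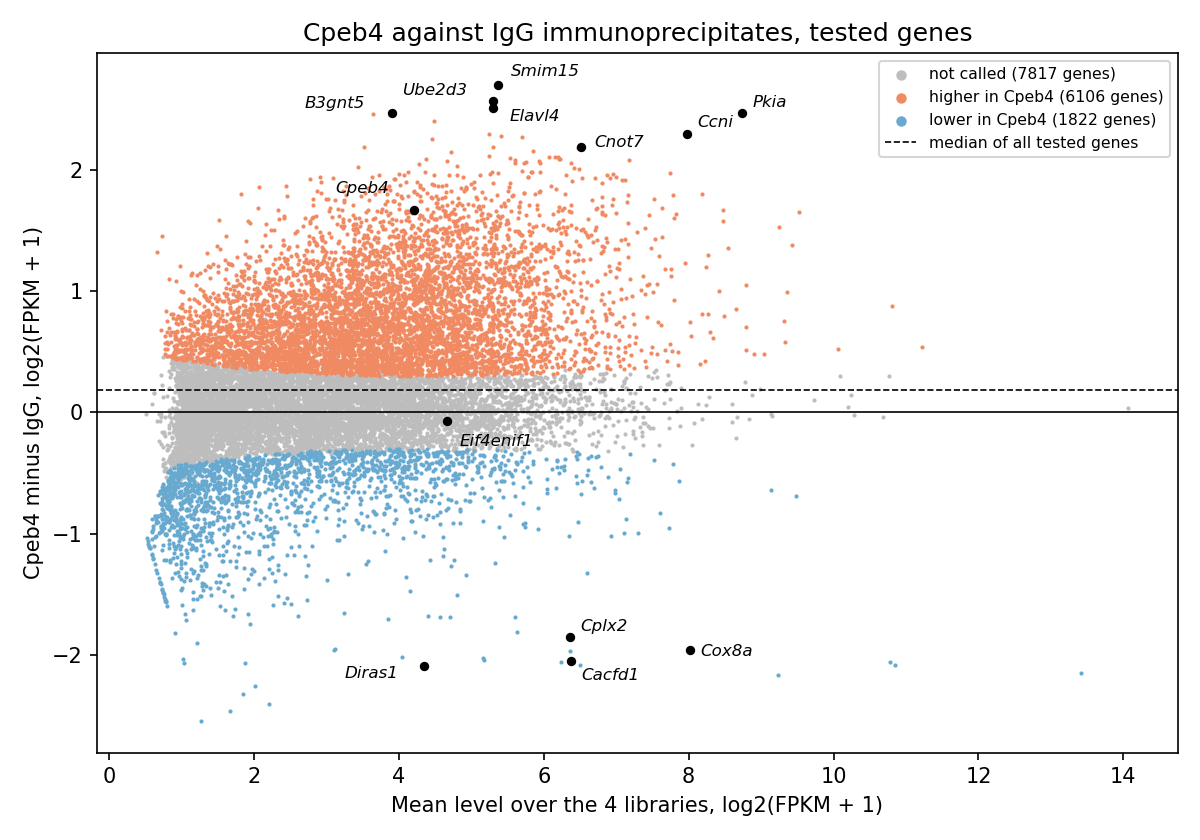
Log2 fold change of Cpeb4 over IgG immunoprecipitates (y axis, log2(FPKM + 1)) against the mean level over all 4 libraries (x axis, same unit) for 15745 tested genes, 1 point per gene. With the authors' scaling, 6106 genes were higher (orange) and 1822 lower (blue), and the dashed line marks the median of all tested genes at 0.19; black points are genes named in the text.

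The mRNA of the antibody's target was measured first. Cpeb4 (chromosome 11: 31870104 to 31935635, GRCm38) was at 32.5 ± 8.18 FPKM (mean ± SD, n = 2) in Cpeb4 immunoprecipitates and 9.35 ± 0.44 (n = 2) in IgG, 3.19-fold higher on the FPKM + 1 scale. Its log2 fold change was 1.67 (SE 0.13, limma adjusted p = 9.59e-08). Among its paralogs, Cpeb2 was higher at 17.2 ± 3.61 against 7.63 ± 0.013 FPKM, a log2 fold change of 1.06 (SE 0.13, limma adjusted p = 6.42e-06). Cpeb3 was at 7.11 ± 1.21 against 3.85 ± 0.46 FPKM with a log2 fold change of 0.74 (SE 0.14, limma adjusted p = 0.000501). The Cpeb3 call was lost with libraries scaled to read totals (log2 fold change 0.30, limma adjusted p = 0.0607) and with no filter on low values (limma adjusted p = 0.0537). Cpeb1 was at 2.74 ± 0.20 against 2.47 ± 0.24 FPKM and was not called (log2 fold change 0.11, SE 0.15, limma adjusted p = 0.585). Eif4enif1, which encodes the P-body protein 4E-T named in the study's title, was at 23.8 ± 0.25 FPKM in Cpeb4 immunoprecipitates and at 25.5 and 24.6 FPKM in the IgG libraries of experiments 1 and 2 (SD 0.60). It was not called (log2 fold change -0.07, SE 0.12, limma adjusted p = 0.66) with the authors' scaling but was called lower under each of the other 4 scalings, at log2 fold changes of -0.57 to -0.33. The level of an mRNA in these precipitates does not measure the amount of its protein.

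The transcripts with the largest positive changes were all higher under each scaling. Smim15 was at 106 ± 24.1 FPKM in Cpeb4 and 15.2 ± 0.185 in IgG immunoprecipitates, 6.5-fold higher on the FPKM + 1 scale (log2 2.70, SE 0.14, limma adjusted p = 1.03e-08). Ube2d3, a ubiquitin-conjugating enzyme, was 5.93-fold higher at 96.3 ± 20.7 against 15.2 ± 1.02 FPKM (log2 2.57, SE 0.14). Elavl4 (HuD) was 5.69-fold higher at 92.8 ± 7.19 against 15.5 ± 1.04 FPKM (log2 2.51, SE 0.13). The glycosyltransferase B3gnt5, the protein kinase A inhibitor Pkia and Lysmd3 had log2 fold changes of 2.47, 2.47 and 2.46 (SE 0.15, 0.17 and 0.14). Pkia was the most abundant of the 10, at 1015 ± 209 against 181 ± 12.5 FPKM. The G protein subunit Gng10, cyclin I (Ccni), the V-ATPase assembly factor Vma21 and the proteoglycan Spock3 followed with log2 fold changes of 2.41, 2.30, 2.30 and 2.28 (SE 0.12, 0.15, 0.15 and 0.16). The limma adjusted p of these 10 genes lay between 1.03e-08 and 5.51e-08, and Gng10, Elavl4, Smim15, Ube2d3 and Lysmd3 had the smallest unadjusted p of all genes. In genomic position (GRCm38), Smim15 lies on chromosome 13 from 108044474 to 108049146, Ube2d3 on chromosome 3 from 135438232 to 135468214 and Elavl4 on chromosome 4 from 110203737 to 110351939.

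Among the transcripts with the largest negative changes, the small GTPase Diras1 was at 8.88 ± 1.14 FPKM in Cpeb4 and 40.9 ± 2.87 in IgG immunoprecipitates (chromosome 10: 81019589 to 81025835), a log2 fold change of -2.09 (SE 0.13, limma adjusted p = 4.06e-08). Cacfd1 was at 39.7 ± 2.38 against 167 ± 6.42 FPKM (log2 -2.05, SE 0.13). Cox8a, a cytochrome c oxidase subunit, was at 131 ± 5.99 against 511 ± 16.1 FPKM (chromosome 19: 7215158 to 7217616, log2 -1.96, SE 0.14). Cplx2, a complexin of the synaptic fusion machinery, was at 42.4 ± 2.51 against 156 ± 20.6 FPKM (log2 -1.85, SE 0.13). The collagen prolyl hydroxylase P4ha3, Lhfpl4 and Fam160b2 had log2 fold changes of -1.69, -1.69 and -1.68 (SE 0.12, 0.13 and 0.12). Cdr1, Fau-ps2 and n-R5-8s1 had log2 fold changes of -1.96, -1.95 and -1.70 (SE 0.13, 0.14 and 0.16). These last values are uncertain, because Cdr1 overlaps a circular RNA on the opposite strand, which an assay without strand cannot separate, Fau-ps2 is a pseudogene of Fau, and n-R5-8s1 is a copy of the repeated 5.8S ribosomal RNA. The limma adjusted p of these 10 genes lay between 4.06e-08 and 4.09e-07.

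**Figure D2:**
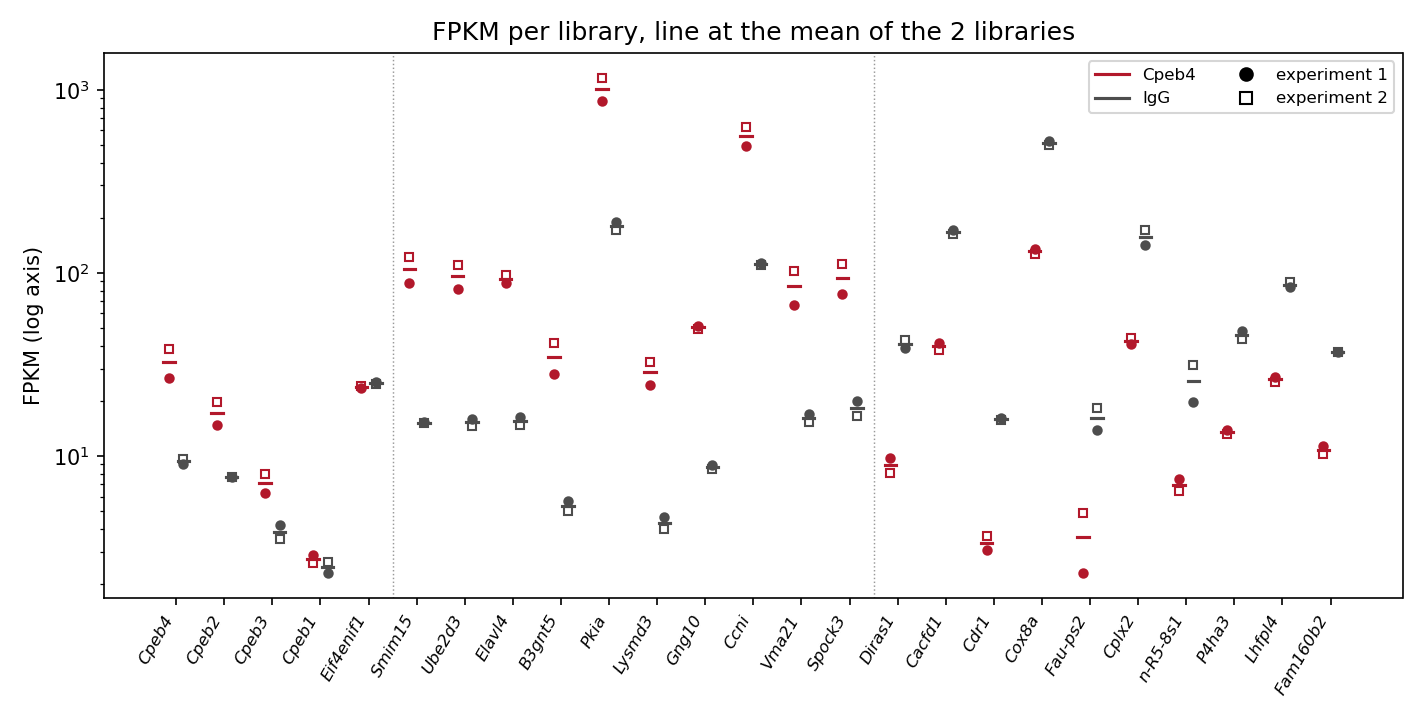
FPKM (y axis, log scale) of the Cpeb family and Eif4enif1 (left), the 10 genes with the largest positive (middle) and the 10 with the largest negative log2 fold change (right). Circles are experiment 1, squares experiment 2 and short lines the mean of the 2 libraries of each antibody, Cpeb4 in red and IgG in grey; Cpeb4 mRNA had means of 32.5 and 9.35 FPKM, while the Eif4enif1 symbols of both antibodies overlap.

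Gene lists fixed before the data were examined were compared with all other tested genes by camera, a competitive set test with a preset correlation of 0.01 between genes, so a list's direction is relative to the other genes. Of 27 lists, 6 stood higher and 7 lower at an adjusted p under 0.05. With the correlation estimated for each list, all 13 calls were lost, at an adjusted p of 0.644 for the zinc finger list and 0.509 for the other 12. That form of camera rests on the 1 residual degree of freedom and has little power, so these losses cannot be credited to correlation between genes. The estimated correlation was below 0.01 for some of these lists (ependymal -0.059, oligodendrocyte -0.011) and above it for others (zinc finger 0.13, oxidative phosphorylation 0.072). With a filter of 50 reads the oligodendrocyte, microglia, choroid plexus and blood, Sox and basic helix-loop-helix, zinc finger, and Notch, Wnt, Bmp and Shh lists lost their calls (camera adjusted p between 0.0504 and 0.085), and with limma-voom the first 4 of these (camera adjusted p between 0.0603 and 0.0761). With a trend on gene length and mean level removed, chosen after seeing the data, 8 of the 13 calls were lost, at camera adjusted p = 0.273 for P-body, 0.519 for neuroblast, 0.461 for oligodendrocyte, 0.137 for microglia, 0.137 for choroid plexus and blood, 0.296 for ribosomal, 0.0814 for Sox and basic helix-loop-helix and 0.519 for Notch, Wnt, Bmp and Shh genes. The member counts given for each list hold over all genes tested and with the authors' scaling unless stated.

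P-body and mRNA decay components stood higher than other genes (camera adjusted p = 0.0103; adjusted p = 0.509 with an estimated correlation), a call lost with the length and level trend removed (camera adjusted p = 0.273). Of 39 members tested, 24 were higher, 2 lower and 13 not called, 15 of the higher ones under all 5 scalings; adjusted over the list alone, 24 were higher and 3 lower. The deadenylase subunits Cnot7, Cnot6l and Cnot6 had log2 fold changes of 2.19, 1.96 and 1.71, and the helicase Ddx6 1.82 (limma adjusted p between 4.4e-08 and 9.17e-08). The lower members were Pan2 at -0.60 (limma adjusted p = 0.000835) and the decapping scaffold Edc4 at -0.39 (limma adjusted p = 0.0159). Of 19 members of the CPEB family and cytoplasmic polyadenylation machinery, 11 were higher (6 under all 5 scalings), 1 lower and 7 not called, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.103). Besides Cpeb4, the poly(A) polymerases Papd4 (Gld2) and Papola were higher at log2 1.41 and 1.36, and the nuclear poly(A)-binding protein Pabpn1 was lower at -1.02. Of 68 translation initiation and elongation factors, 34 were higher (15 under all 5 scalings), 4 lower and 30 not called, also adjusted over the list alone (camera adjusted p = 0.118). Among them Eif5a2, Eif1ax, Eif3e and the cap-binding Eif4e had log2 fold changes of 1.84, 1.62, 1.45 and 1.36, while Eif1b was lower at -0.51.

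Neuroblast and interneuron lineage genes stood higher than other genes (camera adjusted p = 0.00735; adjusted p = 0.509 with an estimated correlation), a call lost with the length and level trend removed (camera adjusted p = 0.519). Of 36 members, 23 were higher, 2 lower and 11 not called, 15 of the higher ones under all 5 scalings; adjusted over the list alone, 25 were higher and 2 lower. Dcx, a microtubule-associated protein of migrating neuroblasts, was higher at log2 1.56 (limma adjusted p = 1.21e-07), Sox4 at 1.53, Etv1 at 1.34 and Sox11 at 1.20. Dlx6 was lower at -1.04 (limma adjusted p = 1.07e-05) and its antisense transcript Dlx6os1 higher at 1.5 (limma adjusted p = 6.75e-07); the cDNA kit does not mark strand, so reads where these genes overlap cannot be assigned. Neural stem cell and radial glia markers were not called as a list (camera adjusted p = 0.17): of 30 members, 14 were higher (10 under all 5 scalings), 1 lower and 15 not called, with the same counts adjusted over the list alone. Ptprz1, Id4, Sox9 and Sox2 had log2 fold changes of 1.28, 1.34, 1.04 and 0.90, and the intermediate filament gene Nes was lower at -0.40. Transit amplifying and cell cycle genes went both ways (camera adjusted p = 0.944): of 38 members, 16 were higher (5 under all 5 scalings), 5 lower and 17 not called, and adjusted over the list alone 16 were higher and 6 lower. Ccne2, Rrm2 and Bub1 were higher at log2 1.20, 1.06 and 1.05, and E2f1 and Mki67 lower at -0.82 and -0.62.

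Oligodendrocyte lineage markers stood higher than other genes (camera adjusted p = 0.025; adjusted p = 0.509 with an estimated correlation). Of 20 members, 15 were higher, 0 lower and 5 not called, and adjusted over the list alone 16 were higher; 5 were higher under all 5 scalings. The galactolipid enzyme Ugt8a and Lhfpl3 had log2 fold changes of 1.79 and 1.73 (limma adjusted p = 8.3e-08 and 9.17e-08). The list's call was lost with libraries scaled to read totals (camera adjusted p = 0.0725) or by upper quartile (camera adjusted p = 0.0589). Astrocyte markers were not called as a list (camera adjusted p = 0.799), with 9 of 20 higher (2 under all 5 scalings), 2 lower and 9 not called, also adjusted over the list alone. The water channel Aqp4 was higher at log2 2.10 and the transporter Slc7a10 lower at -0.81. Of 25 mature and striatal neuron markers, 13 were higher (7 under all 5 scalings), 0 lower and 12 not called, also adjusted over the list alone (camera adjusted p = 0.262), among them Foxp1 at log2 1.16 and the dopamine receptor Drd1 at 0.89.

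Markers of ependymal, vascular, blood and microglial cells stood lower than other genes. Of 18 ependymal markers, 6 were lower, 0 higher and 12 not called (camera adjusted p = 0.000615; adjusted p = 0.509 with an estimated correlation), with 5 lower adjusted over the list alone; Tmem212 had a log2 fold change of -0.69 and Ccdc153 -0.56. Of 18 endothelial and mural markers, 4 were lower, 1 higher and 13 not called, also adjusted over the list alone (camera adjusted p = 0.0147; adjusted p = 0.509 with an estimated correlation), with Ly6c1 at -1.18 and the pericyte gene Rgs5 at 0.96. The vascular call was lost with no filter on low values (camera adjusted p = 0.398). Of 7 choroid plexus and blood markers, 3 were lower and 4 not called, also adjusted over the list alone (camera adjusted p = 0.0374; adjusted p = 0.509 with an estimated correlation). The 3 were erythroid genes, the haem synthesis enzyme Alas2 at -0.45 and the globins Hba-a1 at -0.59 and Hbb-bs at -0.52, the globins being uncertain because near-identical copies share their reads. Of 20 microglia markers, 8 were lower, 3 higher (2 under all 5 scalings) and 9 not called, also adjusted over the list alone (camera adjusted p = 0.0466; adjusted p = 0.509 with an estimated correlation). The chemokine receptor Cx3cr1 and Fcer1g were both lower at -1.02, while the purinergic receptor P2ry12 was higher at 1.23; the list's median was 0.02 and its mean -0.04. The microglia call was lost without the experiment block (camera adjusted p = 0.0555), by upper quartile (camera adjusted p = 0.0504), without Cpeb4 replicate 2 (camera adjusted p = 0.103) and without IgG replicate 1 (camera adjusted p = 0.109). The choroid plexus and blood call was lost without the same libraries (camera adjusted p = 0.0729 and 0.0781), with read totals and by upper quartile (camera adjusted p = 0.0504 for each) and with no filter on low values (camera adjusted p = 0.589).

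**Figure D3:**
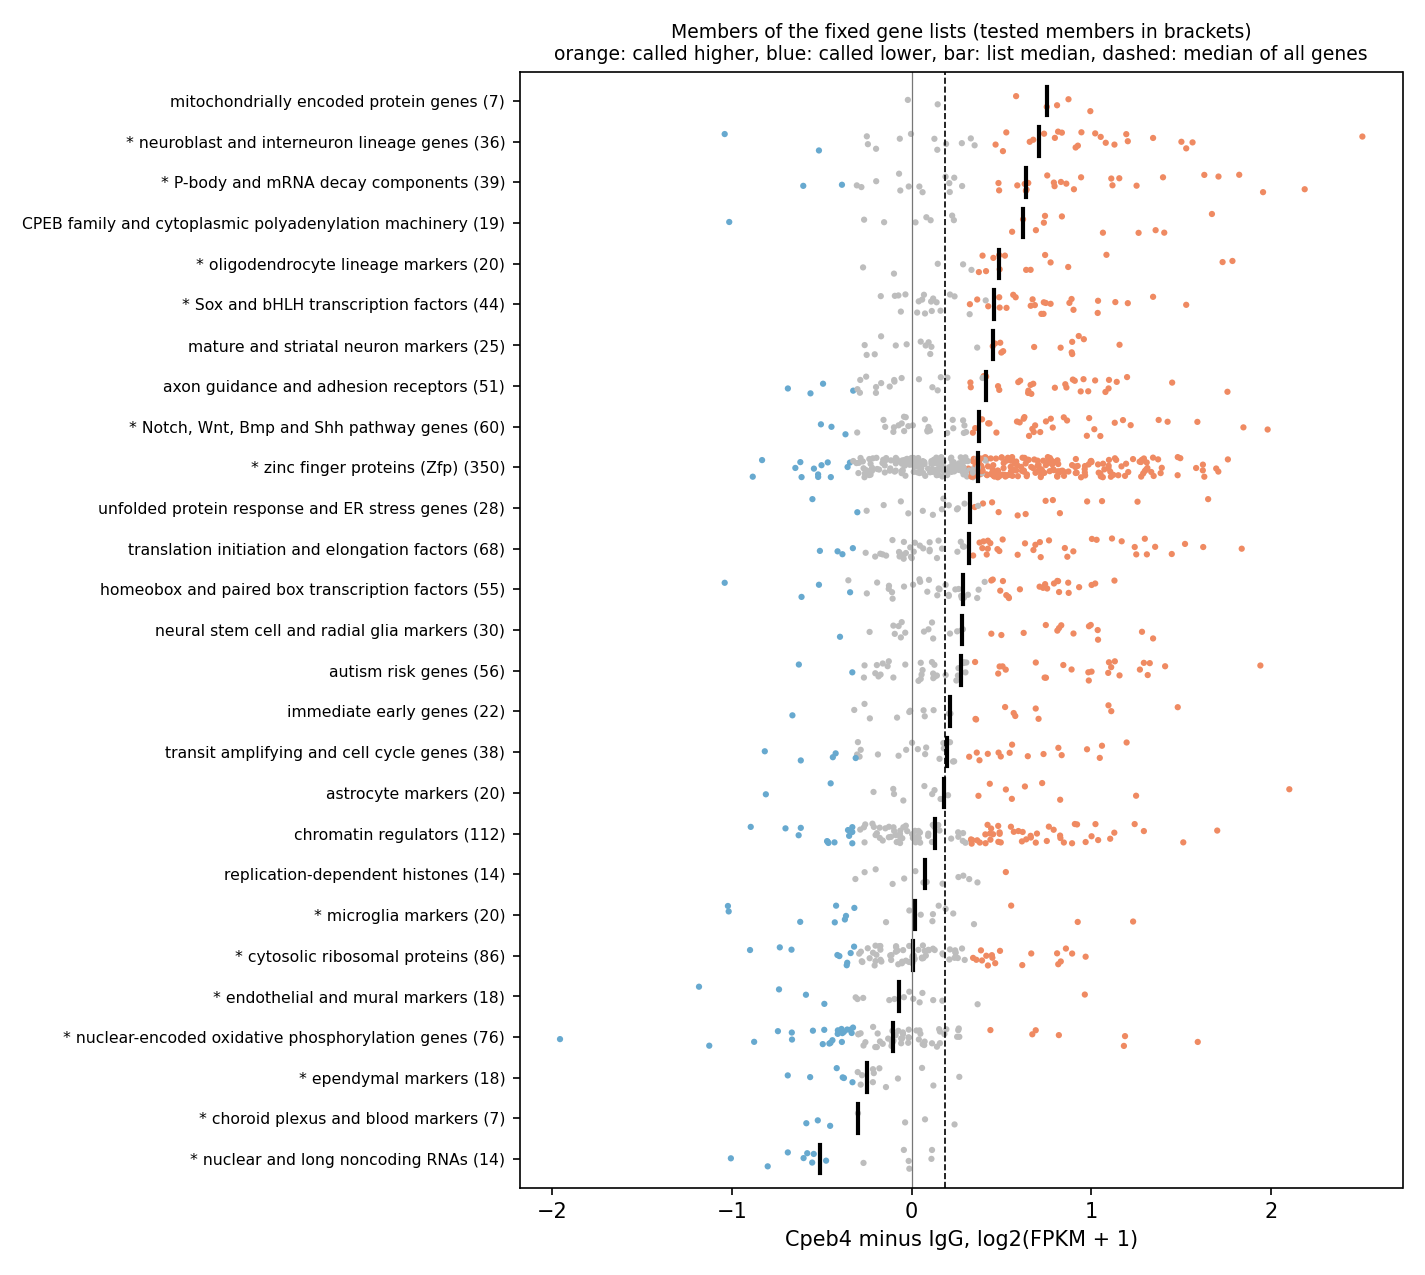
Log2 fold change of Cpeb4 over IgG (x axis, log2(FPKM + 1), authors' scaling) for the tested members of 27 gene lists, 1 point per gene. Orange points were called higher and blue ones lower, bars mark list medians, and the dashed line marks the median of all tested genes (0.19). Asterisks mark the 13 lists called by camera, none of which was called with an estimated correlation, a test with 1 degree of freedom and little power. Nuclear and long noncoding RNAs had the lowest median, -0.51.

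Sox and basic helix-loop-helix transcription factors stood higher than other genes (camera adjusted p = 0.0253; adjusted p = 0.509 with an estimated correlation). Of 44 members, 25 were higher (11 under all 5 scalings), 0 lower and 19 not called, and 26 were higher adjusted over the list alone; besides Sox4 and Sox11, Tcf12 was higher at log2 1.13 and Sox21 at 1.04. The call was lost with libraries scaled to read totals (camera adjusted p = 0.0725) or by upper quartile (camera adjusted p = 0.0504). Of 350 zinc finger genes with a Zfp symbol, 182 were higher (82 under all 5 scalings), 13 lower and 155 not called, and 188 and 13 adjusted over the list alone (camera adjusted p = 0.0138; adjusted p = 0.644 with an estimated correlation). Zfp24 and Zfp2 had log2 fold changes of 1.70 and 1.71, and the list also holds Zfp36l1, at 1.63, which encodes an mRNA decay factor. Without Cpeb4 replicate 2 the zinc finger call was lost (camera adjusted p = 0.0729). Notch, Wnt, Bmp and Shh pathway genes stood higher (camera adjusted p = 0.0443; adjusted p = 0.509 with an estimated correlation), with 32 of 60 higher (15 under all 5 scalings), 3 lower and 25 not called, also adjusted over the list alone. The receptors Bmpr1a and Fzd3 had log2 fold changes of 1.98 and 1.85 and the Wnt effector Tcf7l2 1.59. That call was lost under each of the other 4 scalings (camera adjusted p between 0.0512 and 0.0725), without Cpeb4 replicate 1 (camera adjusted p = 0.0599) and without IgG replicate 1 (camera adjusted p = 0.114).

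Homeobox and paired box factors (22 higher, 10 of them under all 5 scalings, 4 lower and 29 not called of 55; 22 and 3 adjusted over the list alone) were not called as a list (camera adjusted p = 0.335), and Tshz1 had a log2 fold change of 1.13. Chromatin regulators went both ways (46 higher, 17 of them under all 5 scalings, 13 lower and 53 not called of 112, also adjusted over the list alone; camera adjusted p = 0.944). The Polycomb gene Bmi1 was higher at log2 1.70, while the histone methyltransferase gene Ehmt2 was lower at -0.90. Of 56 autism risk genes, 24 were higher (16 under all 5 scalings), 2 lower and 30 not called, also adjusted over the list alone (camera adjusted p = 0.118, and called higher without Cpeb4 replicate 1 at camera adjusted p = 0.0366), with Spast at log2 1.41 and Fmr1 at 1.27. Axon guidance and adhesion receptors (30 higher, 15 of them under all 5 scalings, 4 lower and 17 not called of 51; 31 and 6 adjusted over the list alone) were not called by camera (adjusted p = 0.118). The rotation test fry, which asks whether a list's own genes move one way, called this list alone among the 27 (adjusted p = 0.0481). Many other lists lay just above the threshold at a fry adjusted p of 0.0511, among them the P-body, oligodendrocyte, and Sox and basic helix-loop-helix lists. The fry call therefore does not set axon guidance and adhesion receptors apart. Cntn1 and Epha3 had log2 fold changes of 1.76 and 1.45, and Ephb3 was lower at -0.69. Unfolded protein response genes (13 higher, 5 of them under all 5 scalings, 2 lower and 13 not called of 28, also adjusted over the list alone; camera adjusted p = 0.23) included the chaperone gene Dnajc3 at log2 1.65. Of 22 immediate early genes, which respond to tissue handling, 10 were higher (3 under all 5 scalings), 1 lower and 11 not called, also adjusted over the list alone (camera adjusted p = 0.727), with Klf6 at log2 1.48 and Ier3 at -0.66.

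Nuclear-encoded oxidative phosphorylation genes stood lower than other genes (camera adjusted p = 0.00012; adjusted p = 0.509 with an estimated correlation). Of 76 members, 23 were lower, 7 higher (3 under all 5 scalings) and 46 not called; adjusted over the list alone, 21 were lower and 7 higher. Atp5g2 and Cox6b1 had log2 fold changes of -1.13 and -0.88, while cytochrome c (Cycs) and the complex III subunit Uqcrc2 were higher at 1.59 and 1.18. The list's call was lost with no filter on low values (camera adjusted p = 0.208). Of 7 mitochondrially encoded protein genes, 5 were higher and 2 not called, also adjusted over the list alone (camera adjusted p = 0.262, and called higher without Cpeb4 replicate 1 at camera adjusted p = 0.0204), mt-Nd4 at log2 0.99 being the member higher under all 5 scalings. Cytosolic ribosomal protein genes stood lower than other genes (camera adjusted p = 0.0466; adjusted p = 0.509 with an estimated correlation), although 18 of 86 were higher, 9 lower and 59 not called, and 18 and 8 adjusted over the list alone. Under all 5 scalings 5 of the 18 were higher. The other scalings could end calls of higher genes but not of lower ones, so these 5 cannot be weighed against the 9 lower members. The median log2 fold change of the ribosomal list was 0.01 and its mean 0.06, both above 0 but below the other genes. Rps7 was higher at log2 0.97 and Rpl39 and Rpl38 lower at -0.90 and -0.73, values that reads shared with processed pseudogenes make uncertain. The ribosomal call was lost without Cpeb4 replicate 2 (camera adjusted p = 0.103), IgG replicate 1 (camera adjusted p = 0.0781) or IgG replicate 2 (camera adjusted p = 0.0517).

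Nuclear and long noncoding RNAs stood lower than other genes (camera adjusted p = 0.000546; adjusted p = 0.509 with an estimated correlation). Of 14 members, 8 were lower, 0 higher and 6 not called, also adjusted over the list alone. Gas5 had a log2 fold change of -0.80 (limma adjusted p = 4.89e-05), Miat -0.54 and Snhg1 -0.58. Of 14 replication-dependent histone genes, 1 was higher (0 under all 5 scalings) and 13 were not called, also adjusted over the list alone (camera adjusted p = 0.371). The cDNA was primed on poly(A) tails, so mRNAs without such tails are poorly measured, and the lack of histone calls does not show absence of binding.

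The authors' deposited table of their own comparison held 4920 genes higher and 1119 lower at an adjusted p under 0.05, of 22709 genes with an adjusted p. Among 15290 genes adjusted in both, the authors' deposited table called 4879 higher and limma 6073, of which 4864 were shared where independent lists would share 1937.9. For lower calls the authors' deposited table held 803 and limma 1599, with 795 shared where independent lists would share 84. In opposite directions, limma and the authors' deposited table called 0 genes. Both comparisons rest on the same libraries and scaling, so the overlap describes the tests and not a second experiment.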

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

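Trimmed mean of M-values, centring on the median, subtraction of silent-gene density and removal of the length and level trend were chosen after seeing the data. The count of genes higher in Cpeb4 (6106) was 2759 with libraries scaled to read totals, 3101 by upper quartile, 3718 centred on the median, 3915 with no filter on low values (46911 genes tested), and 1704 with at least a 2-fold change. The count of lower genes (1822) was 6670, 5841, 4715, 875 and 279 under the same settings and 3900 with trimmed mean of M-values. Without 1 library at a time, fitted with no block and with the lone sample of an antibody assumed to vary like the other pair, higher calls ranged from 3977 to 6534 and lower calls from 867 to 2497. With no replicate block, 6007 genes were higher and 1714 lower, of which 5907 and 1660 were also called with the block, 6 lists were higher and 6 lower, and the microglia list lost its call; no other list and none of the 25 genes of the Cpeb family, Eif4enif1 and the largest changes crossed the threshold with the block left out. Other counts stayed within 1.5 times, among them limma-voom with 6439 higher and 1853 lower and a filter of 50 reads with 6447 and 1819. The authors' deposited table held 582 lower genes at an adjusted p under 0.01.

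The lists higher than other genes, 6 with the authors' scaling, numbered 3 with libraries scaled to read totals, 3 by upper quartile, 2 with the filter of 50 reads, 1 with the length and level trend removed and the replicate block kept and 0 with an estimated correlation, while 19 were higher with no filter, where the list is set against many genes near 0. The 7 lower lists numbered 2 with no filter and 0 with an estimated correlation. Fry, which tests a list against no change and not against other genes, called 1 list higher and 0 lower, with many others just above the threshold (fry adjusted p = 0.0511). Without 1 library at a time, 5 to 7 lists were higher and 4 to 7 lower, and without Cpeb4 replicate 1 the mitochondrially encoded (0.0204) and autism risk (0.0366) lists became called higher. List directions turned in these cases, given as adjusted p. With no filter these were cell cycle genes (0.000439), microglia (0.949), ribosomal proteins (0.119), histones (0.581) and chromatin regulators (1.58e-06). Without 1 library, cell cycle genes ranged from 0.808 to 0.976 and turned without Cpeb4 replicate 1 and without IgG replicate 1 (0.972), and chromatin regulators ranged from 0.567 to 0.842 and turned without Cpeb4 replicate 1 and without IgG replicate 2 (0.798). Fry gave an upward sign for cell cycle genes (0.104), ribosomal proteins (0.231), histones (0.223) and chromatin regulators (0.0511), which camera placed below other genes; both can hold at once, since the median of all genes was above 0. Astrocyte markers turned with read totals (0.924), upper quartile (0.84), median centring (0.935) and the length and level trend removed (0.296), and that removal also turned mature neurons (0.561), histones (0.491), autism risk genes (0.323) and axon guidance receptors (0.519), while chromatin regulators became called lower (0.00301). Cpeb1, not called, had log2 fold changes of -0.27 with read totals, -0.22 by upper quartile, -0.09 with trimmed mean of M-values and -0.14 centred on the median. Each of these scalings multiplies all genes of a library by 1 factor, and for the other changes the cause was not tested. The planned edgeR and DESeq2 tests, and the planned settings of the search for polyadenylation elements, were not run. Libraries held 22486721 to 35037171 reads, and how depth limits the calls at each level was not tested.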

Other observations

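The gene families, RNA classes, bins of gene length and satellite-derived genes in this part were chosen after the data had been seen, as were the tests on scaling, on weakly covered genes, on summed satellite reads, on list calls with length and level removed and on lower calls after subtraction of silent-gene density. Among 131 symbol families outside the fixed lists, the share of members called was compared with that of other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Genes are not independent replicates, and these shares hold with the authors' scaling. Values within strata of gene length and level came from another test, a normal approximation summed over bins of length and level. It is rough for small families, so its p-values cannot be compared in size with those of Fisher's exact test. Ubiquitin-conjugating enzymes and relatives with Ube symbols had 28 of 40 members higher and 0 lower (adjusted p = 0.0302), where 42% of all genes compared were higher with the authors' scaling. The call was lost within strata of gene length and level (adjusted p = 0.172). Under all 5 scalings 17 of the 28 were higher. Ube2l3 had a log2 fold change of 1.51 and Ube2g1 1.48. Arl small GTPases and their partners had 17 of 22 higher and 0 lower (adjusted p = 0.041; 0.0601 within the strata, also lost), 12 under all 5 scalings, with Arl5a at log2 1.63 and Arl8b at 1.35. The clustered protocadherins of the Pcdhb group, adhesion proteins of neurons, had 15 of 18 higher and 0 lower (adjusted p = 0.0302; 8.58e-06 within the strata), 5 under all 5 scalings, with Pcdhb3 at log2 0.82. Genes with Ccdc symbols (coiled-coil domain proteins) were higher less often than other genes, 26 of 102 (adjusted p = 0.0302; 0.565 within the strata, also lost), and 13 were lower. Pcdhb members are similar in sequence and many lie near 1 FPKM, so single members are uncertain.

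Loci of microRNAs were lower in 65 of 124 cases (Fisher adjusted p = 1.66e-32, and 5.85e-08 within the strata). They were higher in 20, a low share (Fisher adjusted p = 8.93e-08) whose call was lost within the strata (0.776). Here cDNA primed on poly(A) tails does not measure mature microRNAs, and reads of host genes can overlap these loci. Genes of the microRNA class held few reads, 0.016% and 0.015% in Cpeb4 and 0.019% and 0.022% in IgG libraries. The strata are wide bins of length, so a call kept within them is not free of length for such short loci. By RNA class, 42.7% of protein-coding genes were higher and 8% lower, 24.4% of long noncoding RNAs were higher and 19.8% lower, and 6.6% of small nucleolar RNA genes were higher and 34% lower. The small nucleolar class held only 0.003% of reads in each Cpeb4 library and 0.006% and 0.007% in IgG libraries. RNAs without poly(A) tails are poorly measured by this cDNA. Of 17 Snord genes tested as a family, 3 were higher and 4 lower, and neither share was called (Fisher adjusted p = 0.442 and 0.498). Collagen genes had 7 of 24 members lower and 3 higher, with Col3a1 at log2 -0.95, Col5a2 at -0.94 and Col4a2 at -0.87. The collagen share was not called across all genes (adjusted p = 0.112) and was called within strata of gene length and level (adjusted p = 0.00354). Kinesins with Kif symbols had 6 of 35 members higher and 2 lower, and the low share of higher members was likewise called within these strata (adjusted p = 0.0172) and not across all genes (adjusted p = 0.0877).

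The excess of higher over lower calls (77% of calls higher) went with the authors' scaling. With libraries scaled to read totals the share was 29.3%, so the balance of calls follows the scaling, which shifts all genes alike. With median-of-ratios factors computed from the tested genes alone the share was 54%, but such factors centre those genes near 0, so this value decides nothing on weakly covered genes pulling the authors' factors, which stays open. A larger amount of RNA recovered by the Cpeb4 antibody is a biological explanation that these relative values could not test. Which scaling is right stays open, since the design holds no spike-in or input library among those analysed here.

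Satellite-derived genes were lower in Cpeb4 immunoprecipitates, 12 predicted genes taken here as satellite-derived (not checked against a genome sequence) having 0.273% and 0.624% of reads in Cpeb4 and 2.62% and 2.57% in IgG libraries. Reads split differently between near-identical copies are argued against, because the summed reads were still 4.12 times higher in IgG in experiment 2, the smaller of the 2 ratios. On 1736 olfactory and vomeronasal receptor genes, which brain tissue hardly transcribes, lay 0.0099% and 0.0127% of reads in Cpeb4 and 0.0612% and 0.0605% in IgG libraries, a Cpeb4 to IgG ratio of at most 0.21, consistent with genomic DNA in the IgG libraries as a candidate source. Genomic DNA spread evenly at the density seen on 1024 of these genes is argued against as the source of most lower calls. That density was 0.0287 to 0.127 FPKM per library, small against the filter of 1 FPKM, and 91.4% of lower calls were kept after its subtraction. Subtracting so little could end few calls, so DNA spread unevenly, as over repeats, was not tested and stays open. Antibody and background change together here, so a difference in RNA yield between antibodies stays open and untested.

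Longer genes were called higher more often, 19.6% of genes in the shortest and 53.1% in the longest of 5 equal bins, with a Spearman rho of 0.301 between length and fold change across genes, which are not independent replicates. Lower calls went the other way, with 26.4% of genes in the shortest and 6.5% in the longest bin. Of the 1822 lower calls, 858 were on weak genes with a mean log2(FPKM + 1) under 2, where 711 genes were called higher. Length and level as the whole cause are argued against for 5 of the 13 list calls (ependymal, endothelial and mural, oxidative phosphorylation, zinc finger and noncoding RNA), which were kept with the trend removed, though with the preset correlation only. For the 8 others the share of the distance from other genes left ran from 16.1% (oligodendrocyte) to 100% (ribosomal proteins, -0.18 before and after), with neuroblast genes at 42.3% and P-body genes at 53.9%, so the lost ribosomal call does not speak for length, and as a set, with a median of 54% between the bounds set for either reading, length cannot be told apart from the lists. Of 6 family calls 33.3% were kept within strata of length and level (Pcdhb higher and microRNA loci lower). Those of Ube (stratified adjusted p = 0.172), Ccdc (0.565), Arl (0.0601) and the low share of higher microRNA loci (0.776) were lost. For Arl the unadjusted p was 0.000939 by Fisher's exact test and 0.00115 by the stratified normal approximation. These are unlike tests, so whether the lost Arl call speaks for length cannot be told. Longer transcripts may also carry more binding sites for Cpeb4, a biological explanation that was not tested.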
